A study of Rhodococcus jostii RHA1 with 12 samples.

How the data were processed

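RNA from 12 cultures of Rhodococcus jostii RHA1, taken here as separate, was measured on 12 arrays of a custom 1-colour Agilent design. This soil actinobacterium has a linear chromosome and the linear plasmids pRHL1, pRHL2 and pRHL3. The labels place 3 cultures in each of 4 groups, formed by the parental strain (WT) or a strain with a deletion of ro02104 and by nitrogen supply. The titles number the replicates of a group, and these numbers were used. Every sample description, however, calls its sample the first of 3 replicates. Whether cultures with the same number came from a shared preculture is not stated. Per the labels' protocols, all cultures grew for 48 h at 30 °C in M9 medium with 10 mM ammonium chloride and 20 mM each of glucose and succinate, were washed, and were then placed in medium that was nitrogen rich or limited for nitrogen. The labels do not state how long the cultures then stayed in that medium. RNA was labelled with Cy3 after amplification.

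Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.7.3.1, and their processed signal is an intensity per spot on a linear scale, after subtraction of background and correction of spatial trends, with no scaling between arrays. The deposited flags, of unit other, mark spots that are well above background, saturated or outliers, per the file headers. The authors' deposited value table holds log2 values per locus tag. Its column medians lay between 4.31 and 4.35, and each column correlated across locus tags with the log2 scanner signal of its own array, at r = 0.987 or higher. The near-equal columns point to a scaling between arrays whose method is not given in the sources used here, and the table carries no ratio and so no direction.

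The arrays held 15208 non-control spots for 9074 probes and 8972 locus tags, of which 8921 had 1 probe and 51 had 3. From the intensities, log2(processed signal) minus the array's 75th percentile over non-control spots was computed. Outlier spots were left out (at most 16 on an array), saturated probes were kept (2 to 4 on an array), spots of a probe were averaged, and the probes of a locus tag were averaged. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which left 6929 probes and 6828 genes. The number of arrays limits the precision, and so does their brightness: the 75th percentile ranged from 21.97 to 152 intensity units, and 49.6% to 92.2% of probes were well above background.

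Group means were fitted for each gene with limma 3.58.1 in R 4.3.3 (lmFit over all 12 arrays, then eBayes), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The contrasts were starved against rich nitrogen in each strain, the deletion strain against WT in each nitrogen condition, the interaction of strain and nitrogen, and the strain effect averaged over both conditions. All adjusted p-values given for genes are from this limma fit, and those for gene lists are from limma's camera with a preset correlation of 0.01, two-sided, adjusted over the 5 lists of a contrast. Camera with an estimated correlation and fry were run as well. For a gene that was not well above background on any array of the dimmer group, the fold is a bound, computed against the higher of the array's lowest signal among probes well above background and the probe's own value, and written as "at least".

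The files pair locus tags with no gene names or products, and genomic coordinates were not used here. Of 26 gene lists fixed before the data were examined, 20 are defined by product descriptions and could not be filled, among them nitrogen assimilation, triacylglycerol synthesis, polyhydroxyalkanoate metabolism and ribosomal proteins. A list of lipid droplet proteins held only ro02104. The 5 lists tested are defined by locus tags: the cholesterol catabolism cluster of this strain, the 20 tags next to ro02104, and the tags of each of the 3 plasmids. The rule for named genes, also fixed beforehand, took for each pairwise comparison ro02104, the 5 genes with the largest rise and the 5 with the largest fall among called genes with a described product and no overlap between the groups, and the called member with the largest rise and fall of each list, with all called genes where there were 10 or fewer. For the interaction and the mean strain effect it took described genes. With no descriptions, the parts of the rule that need them name no gene. The list part was applied to the cholesterol cluster and the tags next to ro02104 and, to keep tags without a name few, not to the plasmid lists. Genes named for the interaction and the mean strain effect were therefore chosen after their values were seen. Runs of at least 6 tested tags that follow each other and passed in the same direction were described after their values were seen, with 1000 shuffles of the tag order as the chance value. Tag order is taken as gene order.

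The fit was tested on simulated data of 6828 genes with 200 changed genes per contrast. It recovered 97.5% of 16-fold changes and 67.0% of 4-fold changes in the contrast of the deletion strain against WT under starvation, and none of 2-fold changes. For the interaction it recovered 93.0% of 16-fold and 18.0% of 4-fold changes. These shares hold for 200 changed genes and for 1 SD per gene over all groups. The data differ: the median gene's SD was 0.67 in starved WT and 0.27 in the starved deletion strain. The starved contrast of the data called 2922 genes, 2711 of them with at least a 2-fold change, so smaller changes were called there. In the simulation of the starved contrast over the same 6828 genes, camera called each of the 5 lists when it was shifted by 1 log2 unit and none when it was not. The simulated genes varied independently, while the estimated correlations within the 5 lists of the data are 0.010 to 0.044. The simulation therefore does not test for false list calls among genes that vary together.

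Slide, taken from the array identifiers in the file headers, was taken as a possible batch. The reported fit has no term for slide, which enters only alternative fits and the changes given within slides. Alternatives fixed before the data were examined were other scalings (median, quantile, none), normexp background correction with an offset of 50 and quantile normalization, the authors' value table, no filter or a stricter filter on dim probes, the brightest probe per gene, array weights, a trended prior, a fit over the 2 groups compared, replicate number or slide as a block, leaving out each array, and a 2-fold threshold. Normexp was planned on mean spot signals and was run on median spot signals, since those are the ones used here. Its offset of 50 shrinks log2 changes of dim signals by construction. Scaling on the E1A spike-in probes and a common floor were added after the brightness of the arrays was seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.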

Results

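The series compares the transcripts of R. jostii RHA1 with those of a strain that lacks ro02104, which the labels call a homolog of TadA. In the related Rhodococcus opacus, TadA is a protein needed for normal storage of triacylglycerol. The design asks what nitrogen starvation does in each strain, what the deletion does in each nitrogen condition, and whether the nitrogen response differs between the strains. Each group holds 3 arrays, taken here as 3 separate cultures.

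The arrays differed in brightness with the groups. The 75th percentile of signal was 21.97 to 31.2 intensity units on the 3 nitrogen-rich WT arrays, 36.5 to 76.3 on the starved WT arrays, 30.9 to 45.7 on the nitrogen-rich deletion arrays and 85.0 to 152 on the starved deletion arrays. Relative to the E1A spike-in probes, it was 1.59% to 2.47%, 2.16% to 4.56%, 1.97% to 4.61% and 7.26% to 9.77% in the same order. The 3 starved WT arrays were also the least alike. The correlation across genes between pairs of them was 0.639 to 0.900, against 0.956 to 0.975 among the starved deletion arrays. The median gene's SD was 0.67 against 0.27 log2 units. Starved WT replicate 2 correlated across genes with the starved deletion arrays at 0.922 to 0.938, and starved WT replicates 1 and 3 did so at 0.469 to 0.741. All 3 starved WT arrays lay on slide 2, with 1 nitrogen-rich WT and 1 starved deletion array. All changes are relative to each array's 75th percentile. Without scaling between arrays, the median of all genes shifted by 1.16 and 1.52 log2 units with starvation in WT and the deletion strain. It shifted by 0.60 and 1.33 with the deletion in nitrogen-rich and starved cultures. With scaling on the E1A spike-in probes, chosen after seeing the data, these shifts were 0.80, 1.21, 0.69 and 1.47. They were 0.07, 0.02, -0.01 and 0.30 with median centring, and 0.16, -0.16, 0.03 and 0.06 in the values reported. Slide 1 held 2 arrays each of nitrogen-rich WT and nitrogen-rich deletion and 1 starved deletion array, and slide 3 held 1 array of each deletion group.

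**Figure D1:**
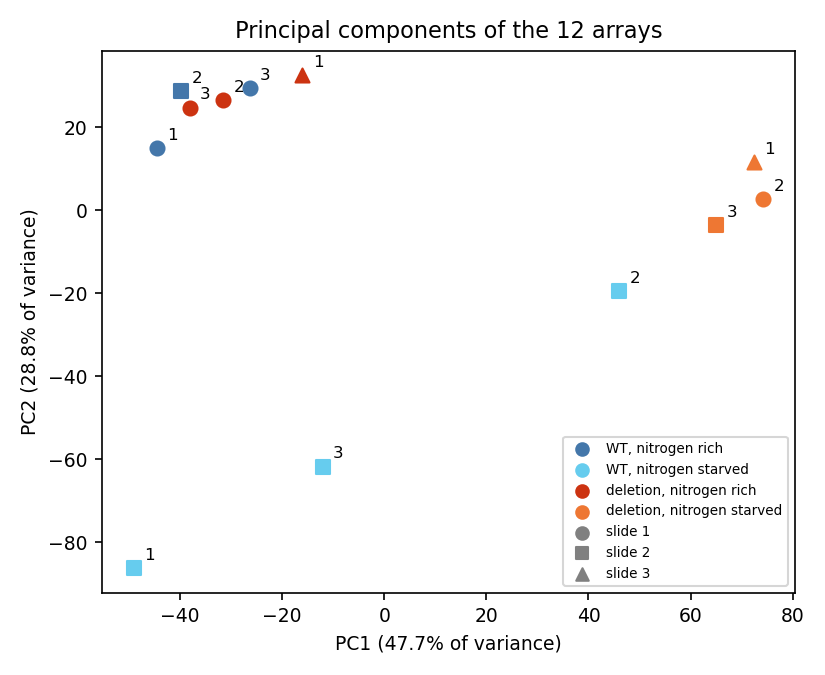
First and second principal component of the normalised log2 values of the genes tested, in arbitrary units, for the 12 arrays, with colour for the group, marker shape for the slide and a number for the replicate. PC1 holds 47.7% of the variance and places starved WT replicate 2 at 46.1, near the starved deletion arrays at 65.0 to 74.3, while starved WT replicates 1 and 3 lie at -49.1 and -12.1.

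The targeted gene was read first as a check of the labels. The ro02104 probe was well above background on all 6 WT arrays and on 0 of the 6 deletion arrays. Its normalised log2 signal was 2.53 ± 0.50 (SD, n = 3) in nitrogen-rich WT and 2.72 ± 0.35 (SD, n = 3) in starved WT. In the deletion strain, ro02104 was at least 64.1-fold lower with nitrogen (adjusted p = 2.26e-06) and at least 168-fold lower without it (adjusted p = 4.05e-07). Nitrogen supply did not detectably change ro02104 in WT (log2 change 0.19, SE 0.43, adjusted p = 0.777).

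**Figure D2:**
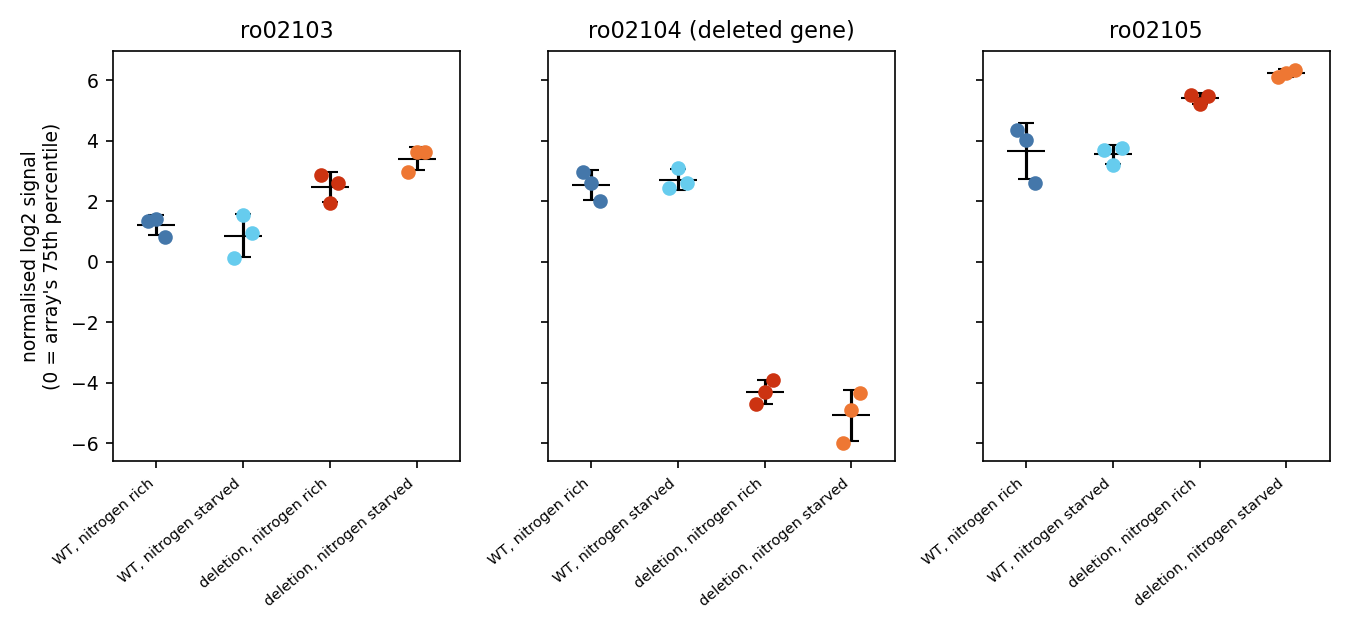
Normalised log2 signal of ro02103, ro02104 and ro02105 on each array (points), with the mean (line) and SD (bars) of the 3 arrays of a group. ro02104 lies at 2.00 or above on the WT arrays and at -3.89 or below on the deletion arrays, and ro02103 and ro02105 have higher group means in the deletion strain in both nitrogen conditions.

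In WT, nitrogen starvation raised and lowered runs of adjacent genes, the longest of which fell. The 24 tags ro06132 to ro06155 all fell, with a median of 6.79-fold: their median signal was 3.43 to 3.60 log2 units on the 3 nitrogen-rich arrays and 0.62 to 1.36 on the 3 starved arrays. The 14 tags ro10043 to ro10056 of pRHL2 fell by a median of 3.90-fold. The 9 tags ro01820 to ro01828 rose by a median of 8.70-fold, with the tags below background in nitrogen-rich WT set to their bounds. The 6 tags ro06365 to ro06370 rose by a median of 54.0-fold, from -3.40 to -1.89 log2 units on the nitrogen-rich arrays to 2.45 to 3.96 on the starved arrays. These runs were singled out after their values were seen. Each kept its direction under every scaling tried, but the falls were smaller without scaling and with spike-in scaling, with log2 medians of -1.77 and -2.13 for ro06132 to ro06155 and -0.97 and -1.33 for ro10043 to ro10056. Normexp with an offset, followed by quantile normalization, gave smaller changes, such as 2.70 for ro06365 to ro06370 and 0.95 for ro01820 to ro01828.

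Of 6828 genes tested, 1263 changed in WT, of which 530 rose and 733 fell. Among 149 tested genes of the cholesterol catabolism cluster, 36 rose, 3 fell and 110 did not pass (38 and 5 adjusted over the list alone). The list's median change was 0.62 log2 units against 0.15 for other genes (0.52 with members at background set to their bounds), and it rose as a list (adjusted p = 3.05e-05; adjusted p = 0.0101 with an estimated correlation). Within it, ro04584 rose 45.5-fold, from -1.10 ± 0.31 to 4.41 ± 0.38 (SD, n = 3; adjusted p = 3.27e-07), and ro04657 fell, with a log2 change of -2.03, from -1.89 ± 1.14 to -3.92 ± 1.04 (SD, n = 3; adjusted p = 0.0293). It was well above background on 1 of the 3 starved arrays, and its change was -1.32 with each value raised to at least the lowest well-above-background signal of its array. Of the 17 tested tags next to ro02104, 3 rose and 0 fell (likewise adjusted over the list alone), led by ro02113 with 2.95-fold (adjusted p = 0.0192). The list did not pass (adjusted p = 0.408). Of 693 pRHL1 genes, 58 rose and 32 fell (30 and 22 adjusted over the list alone). The list rose by a median of 0.38 with adjusted p = 0.0165. This was lost with an estimated correlation (adjusted p = 0.516), with no filter on dim probes (adjusted p = 0.308), and without starved WT replicate 1 or 3 (adjusted p = 0.0991 and 0.0718). The lists of pRHL2 (24 up and 45 down of 351; 24 and 47 adjusted over the list alone) and pRHL3 (16 up and 12 down of 249; 10 and 8 adjusted over the list alone) did not pass, each with adjusted p = 0.408. Over all contrasts, a list's median, mean and test differed in sign in 7 of 30 list tests, 0 of them called.

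The WT count depended on single arrays, on slide and, as given below, on which groups shared the estimate of spread. It was 2666 without starved WT replicate 2, 752 without starved WT replicate 3, 827 without nitrogen-rich WT replicate 2, and 525 with slide as a fixed block. In its split, 95.7% of the called genes rose without scaling and 83.7% with spike-in scaling, against 42.0%. With slide as a block, ro04657 and ro02113 had adjusted p = 0.159 and 0.188. ro04657 also missed the threshold without nitrogen-rich WT replicate 1 or 2 or starved WT replicate 1 or 3 (adjusted p from 0.0551 to 0.129), and ro02113 without nitrogen-rich WT replicate 1 or 3 (adjusted p = 0.0556 and 0.0619). Within slide 2, which holds the 3 starved arrays and 1 nitrogen-rich array, the log2 changes were 5.84 for ro04584, 1.33 for ro02113 and -1.71 for ro04657, and the medians were 0.63 for the cholesterol cluster and 0.50 for pRHL1.

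In the ro02104 deletion strain, starvation moved several of the same runs in the same directions. The tags ro06365 to ro06370 rose by a median of 138-fold, from -2.76 to -2.52 log2 units on the 3 nitrogen-rich arrays to 3.83 to 4.96 on the 3 starved arrays. The 16 tags ro01813 to ro01828 rose by a median of 23.6-fold, with tags below background set to their bounds. The 19 tags ro06137 to ro06155 fell by a median of 4.07-fold and the 10 tags ro02803 to ro02812 by 4.91-fold. The latter also fell in WT, by 7.94-fold. The 11 tags ro04508 to ro04518, part of the cholesterol cluster, rose by a median of 3.58 log2 units with such tags at their bounds. Runs were again singled out after their values were seen. These kept their direction under every scaling, but without scaling and with spike-in scaling the medians were -0.34 and -0.65 for ro06137 to ro06155 and -0.61 and -0.92 for ro02803 to ro02812. Normexp with quantile normalization gave 3.40 for ro06365 to ro06370, 1.31 for ro01813 to ro01828 and 1.46 for ro04508 to ro04518. Of the other falling runs, ro01471 to ro01476 and ro05915 to ro05921 turned, with medians of 0.25 and 0.24 without scaling against -1.44 for each.

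Of the 6828 genes, 1952 changed in the deletion strain, 976 in each direction. In the cholesterol cluster, 40 genes rose, 12 fell and 97 did not pass (41 and 22 adjusted over the list alone), with a median of 0.42 against -0.17 for other genes (adjusted p = 0.00757). That call was lost with an estimated correlation (adjusted p = 0.0678) and without scaling (adjusted p = 0.0558), and the median turned to -0.12 with no filter on dim probes and to -0.32 over probes above background on all arrays (adjusted p = 0.0613 and 0.545). Its member ro04515 rose at least 187-fold, to 4.08 ± 0.20 (SD, n = 3; adjusted p = 6.68e-08), and ro04527 fell 4.63-fold, from -0.95 ± 1.06 to -3.16 ± 0.48 (SD, n = 3; adjusted p = 0.00699). Of the tags next to ro02104, 4 rose and 0 fell (likewise adjusted over the list alone), led by ro02112 with 4.63-fold (SE 0.75 log2 units, adjusted p = 0.0428). The list had adjusted p = 0.117. The plasmid lists did not pass: 85 pRHL1 genes rose and 111 fell (191 passed adjusted over the list alone, 84 of them up; adjusted p = 0.231), 42 pRHL2 genes rose and 45 fell (40 and 43; adjusted p = 0.793), and 66 pRHL3 genes rose and 33 fell (69 and 43; adjusted p = 0.117).

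The deletion-strain count was 1016 without nitrogen-rich deletion replicate 2 and 941 without nitrogen-rich replicate 3. It was 1110, 859 and 1052 without starved deletion replicate 1, 2 or 3, 3147 without starved WT replicate 2, and 1287 with slide as a fixed block. A fit over only the arrays of this strain called more genes, as given below. With each array centred on its median 1160 genes rose and 601 fell, and with normexp 60.8% of the called genes rose. Without scaling, 4191 rose and 16 fell (2947 and 29 with spike-in scaling). ro02112 had adjusted p = 0.0539 with slide as a fixed block, and 0.0511 to 0.119 without any single array of the deletion strain or without replicate 3 of either WT group, and ro04527 had 0.339 without scaling. Within slides 1 and 3, with 1 starved array each, the log2 changes were 8.80 and 8.69 for ro04515, -2.36 and -1.61 for ro04527 and 2.54 and 1.63 for ro02112, and the cholesterol cluster's median was 0.34 and 0.09.

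The nitrogen responses of the strains, which share no array, overlapped. 315 genes rose in both strains, where independent lists would share 75.8, and 316 fell in both, where independent lists would share 105. 2 genes rose in WT and fell in the deletion strain, and 2 did the reverse. Across the 6828 genes, which are not independent replicates, the log2 changes correlated at r = 0.505 (Spearman's rho = 0.324). The correlation was 0.253 without starved WT replicate 2 and 0.696 without starved WT replicate 1.

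**Figure D3:**
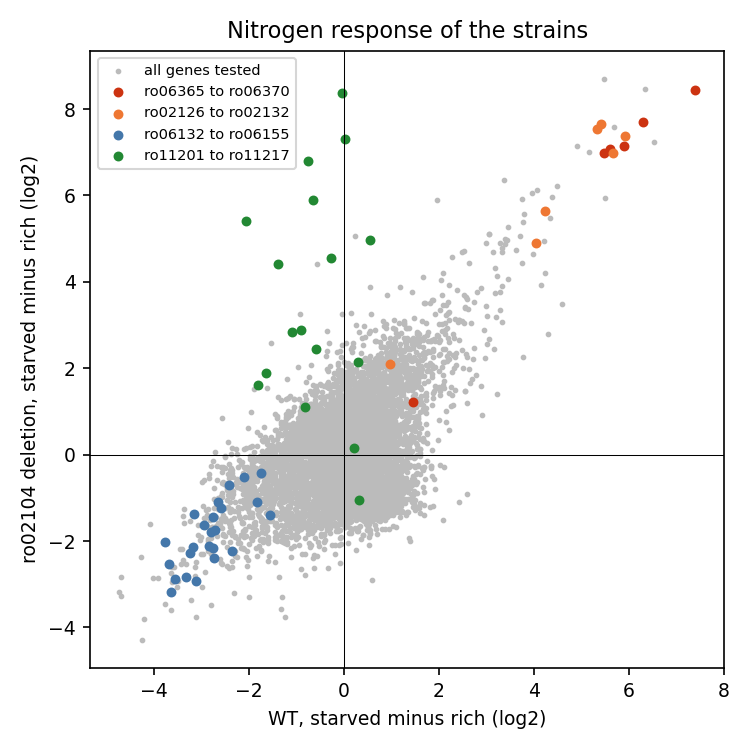
Log2 change from rich to starved nitrogen in WT (x axis) and in the ro02104 deletion strain (y axis), 1 point per gene tested, with 4 tag ranges in colour. The tags ro06365 to ro06370 rose in both strains (medians 5.76 and 7.11), ro06132 to ro06155 have medians of -2.76 and -1.91, and most of ro11201 to ro11217 lie above 0 only on the y axis, with a median of 2.88 in the deletion strain and -0.64 in WT.

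With nitrogen, the deletion strain differed from WT in 5 genes, all lower: ro02104 itself, ro02523 and the pRHL3 tags ro11204, ro11207 and ro11210. ro02523 was lower by at least 3.42 log2 units (adjusted p = 0.0387) and was not well above background on any nitrogen-rich deletion array, against -0.05 ± 1.09 (SD, n = 3) in WT. ro11204 was 4.82-fold lower, at -2.84 ± 0.17 against -0.57 ± 0.65. ro11207 was lower, with a log2 change of -4.25, at -3.23 ± 1.23 against 1.02 ± 0.54. Both were well above background on only 1 of the 3 nitrogen-rich deletion arrays. With values raised to the lowest well-above-background signal of each array, the change of ro11207 was -3.96. ro11210 was 17.5-fold lower, at -1.70 ± 0.51 against 2.43 ± 0.90 (SD, n = 3 throughout; adjusted p = 0.0222 for each of these pRHL3 tags).

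At an unadjusted p under 0.05, limma gave 213 genes in this comparison. No gene of the cholesterol cluster passed (0 also adjusted over the list alone; adjusted p = 0.729 for the list). The tags next to ro02104 were higher as a list, with a median of 0.25 against 0.03 (adjusted p = 0.00436; adjusted p = 0.101 with an estimated correlation and 0.0907 without nitrogen-rich deletion replicate 1), though no single tag passed and 1 did adjusted over the list alone. The pRHL3 list was lower, with 3 genes down (11 adjusted over the list alone). All 3 lie among ro11201 to ro11217, whose median was -2.24 (-0.52 with normexp and quantile normalization), while that of the other 232 pRHL3 genes was -0.03. The list had a median of -0.05 (0.52 without scaling and 0.61 with spike-in scaling, below the shift of all genes) and adjusted p = 0.00267, which became adjusted p = 0.197 with an estimated correlation. pRHL1 (0 genes, also adjusted over the list alone) and pRHL2 (0 genes, 1 down adjusted over the list alone) had adjusted p = 0.729. The count was 1, ro02104, without nitrogen-rich deletion replicate 1 or 3, starved deletion replicate 1, or nitrogen-rich WT replicate 1 or 2. It was also 1 with slide as a fixed block, where ro02523 had adjusted p = 0.348 and ro11204, ro11207 and ro11210 had 0.236. 9 genes were called without starved WT replicate 2 and 8 without starved WT replicate 3. ro02523 also missed the threshold without nitrogen-rich WT replicate 3 (adjusted p = 0.135), and both ro02523 and ro11204 without nitrogen-rich deletion replicate 2 (adjusted p = 0.0740 and 0.0909). Within slide 1, with 2 arrays of each strain, the log2 changes were -4.21 for ro02523, -2.08 for ro11204, -3.75 for ro11207 and -3.57 for ro11210, and the medians of the tags next to ro02104 and of pRHL3 were 0.18 and -0.13.

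Without nitrogen, the deletion strain differed from WT in many more genes, by smaller folds than the leading nitrogen changes apart from ro02104. ro02105, the tag after the deleted gene, was 6.41-fold higher, at 6.24 ± 0.12 against 3.56 ± 0.32 (SD, n = 3; adjusted p = 0.0110), and ro02111 was 2.85-fold lower (adjusted p = 0.0111). In the cholesterol cluster, ro04516 was 6.91-fold higher, at 3.14 ± 0.20 against 0.35 ± 1.39 (SD, n = 3; adjusted p = 0.0188), and ro04683 was 4.62-fold lower, at -2.40 ± 0.25 against -0.19 ± 0.99 (SD, n = 3; adjusted p = 0.0110). Of 693 pRHL1 genes, 47 were higher and 241 lower, including the 9 tags from ro08275 to ro08288, lower by a median of 3.55-fold and singled out after their values were seen. The log2 median of this run was -1.83, and it was -0.57 without scaling, -0.43 with spike-in scaling, -0.49 with normexp and quantile normalization and -0.98 with the common floor, chosen after seeing the data.

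In all, 1300 genes were higher and 1622 lower, or 2922 of 6828. This count uses a spread per gene shared by all groups, although starved WT varied most. A fit over only the arrays compared called far fewer genes, as given below. The pRHL1 list was lower, with a median of -0.49 against 0.13 for other genes (46 up and 241 down adjusted over the list alone; adjusted p = 0.000658), which became adjusted p = 0.445 with an estimated correlation. Its median was 0.78 without scaling and 0.92 with spike-in scaling, below the shift of all genes. The cholesterol cluster had 27 genes higher and 39 lower (the same counts adjusted over the list alone; adjusted p = 0.944). The tags next to ro02104 had 4 higher and 1 lower (likewise; adjusted p = 0.277). pRHL2 had 42 and 58 (23 and 36; adjusted p = 0.944) and pRHL3 had 38 and 60 (36 and 59; adjusted p = 0.944).

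The count for starved cultures was 604 without starved WT replicate 1 and 653 without starved WT replicate 3. It was 1356, 1111 and 1844 without starved deletion replicate 1, 2 or 3, and 3 with slide as a fixed block. With that block the changes of the 2922 genes all kept their direction, which is no independent check since the same arrays chose these genes. The median SE was 0.53 in place of 0.41, while ro02105, ro02111, ro04516 and ro04683 had adjusted p = 0.101. ro04516 had adjusted p = 0.0908 and 0.0623 without starved WT replicate 1 or 3 and 0.0583 without starved deletion replicate 2. Within slide 2, with 3 WT arrays and 1 deletion array, the log2 changes were 2.80 for ro02105, 2.86 for ro04516, -1.54 for ro02111 and -1.94 for ro04683, and the pRHL1 median was -0.48. Median centring gave 1870 higher and 1274 lower genes, no scaling 3519 and 19, and spike-in scaling 3676 and 3. Without scaling, ro04683 and ro02111 had adjusted p = 0.0816 and 0.601.

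The nitrogen response differed between the strains in 15 genes, and 11 of these lie among the 17 pRHL3 tags ro11201 to ro11217, a range singled out after its values were seen. The mean over arrays of the range's median signal was 0.64 ± 0.41 in nitrogen-rich WT and 0.05 ± 0.59 in starved WT, but -1.38 ± 0.36 in the nitrogen-rich and 2.13 ± 0.48 in the starved deletion strain (SD, n = 3). The interaction was largest for ro11202, at 8.39 log2 units (SE 1.08, adjusted p = 0.00297), whose level was -1.40 ± 1.12 in the nitrogen-rich and 6.96 ± 0.57 in the starved deletion strain, against 2.69 ± 1.07 and 2.66 ± 1.60 in WT (SD, n = 3). In the starved deletion strain, 13 of the 17 tags rose against the nitrogen-rich deletion strain, while in WT 0 rose and 1 fell. The other 4 genes lie outside the range. ro05052 changed by 5.065 log2 units in the deletion strain and by 0.25 in WT (interaction 4.82, SE 0.79). It was well above background on only 1 of the 3 nitrogen-rich deletion arrays. Its interaction was 3.34 with the common floor and 1.475 with normexp and quantile normalization. ro08146, ro03851 and ro05301 had a lower change in the deletion strain than in WT (-3.53, -2.78 and -2.40). These 3 sizes rest on values at background, since none of the 3 genes was well above it on any nitrogen-rich WT array. With the common floor the interactions were -0.51, -0.02 and -0.42, and with normexp and quantile normalization -0.50, -0.23 and -0.29. Within the range, ro11203 and ro11206 lost their calls with quantile normalization (adjusted p = 0.0552 and 0.0545), the authors' table (0.0535 each), replicate as a block (0.0755 and 0.0777) and slide as a fixed block (0.109 and 0.119), and in 7 and 6 of the 12 fits that left out 1 array (adjusted p from 0.0562 to 0.103). ro11209 lost its call with normexp and quantile normalization (adjusted p = 0.0760). The 4 calls outside the range were lost with slide as a fixed block (adjusted p from 0.0708 to 0.191) and with the authors' table, and the last 3 also without scaling, with spike-in scaling, with normexp and with the common floor. With slide as a random block, whose estimated correlation between arrays of a slide was -0.15, 14 genes were called. The 4 genes were not tested when probes had to be above background on all arrays. Quantile normalization also ended the calls of ro05052, ro03851 and ro05301, and median centring and replicate as a block those of the last 2. Single arrays mattered too. ro08146 missed the threshold without nitrogen-rich deletion replicate 1 or starved deletion replicate 2 (adjusted p = 0.0550 and 0.0535). ro05052 did so without these, nitrogen-rich deletion replicate 2, starved deletion replicate 1 or nitrogen-rich WT replicate 2 or 3 (adjusted p from 0.0562 to 0.0806). Leaving out 1 array ended the call of ro03851 in 8 of 12 cases and that of ro05301 in 10 of 12 (adjusted p of 0.0643 or more).

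**Figure D4:**
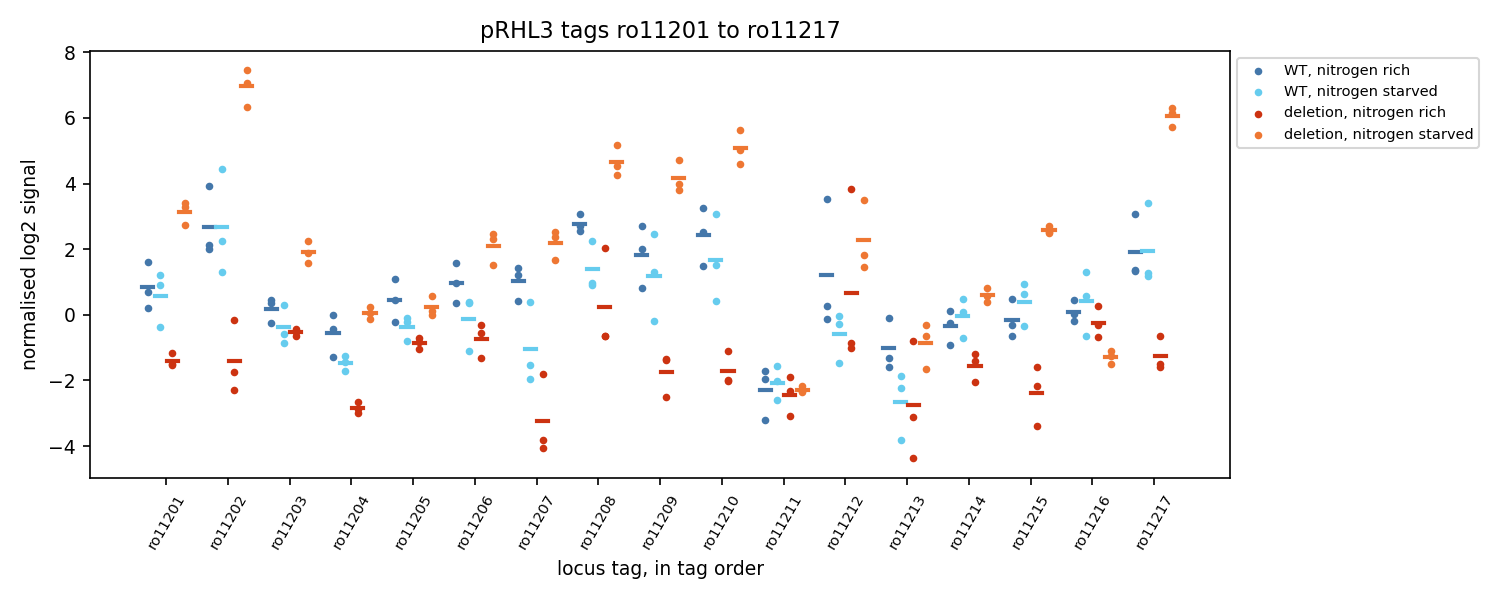
Normalised log2 signal of the 17 pRHL3 tags ro11201 to ro11217, in tag order on the x axis, on each array (points) with the mean of each group of 3 arrays (lines). At ro11202, ro11210 and ro11217 the starved deletion arrays are the highest and the nitrogen-rich deletion arrays the lowest, with WT in between.

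Of the gene lists, pRHL1 alone had an interaction, with a median of -0.51 against 0.08 for other genes and 0 genes up and 1 down (likewise adjusted over the list alone; adjusted p = 0.000771; adjusted p = 0.459 with an estimated correlation). Its median was 0.18 without scaling and 0.23 with spike-in scaling, with the test against other genes still downward. pRHL3 had 11 up and 0 down (13 and 0 adjusted over the list alone) with adjusted p = 0.690. The cholesterol cluster (2 up and 3 down adjusted over the list alone), the tags next to ro02104 and pRHL2 (0 in both, also adjusted over the list alone) had no gene past the threshold, and each list had adjusted p = 0.690. The interaction count was 9 without nitrogen-rich deletion replicate 1 or starved deletion replicate 2, 9 with slide as a fixed block, and 3091 without starved WT replicate 2.

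Averaged over both nitrogen conditions, 8 genes were higher and 13 lower in the deletion strain. Among those called higher were the tags on either side of ro02104, and they are named here after their values were seen. ro02105 was 4.62-fold higher (log2 change 2.21, SE 0.28, adjusted p = 0.00522) and ro02103 3.74-fold higher (1.90, SE 0.28, adjusted p = 0.0165). By size of the rise, ro02105 had rank 2 and ro02103 rank 7 of all genes. With nitrogen alone neither passed (log2 changes of 1.74 and 1.27, adjusted p = 0.336 and 0.9996). Without nitrogen both did (2.68 and 2.54, adjusted p = 0.0110 each). In the mean effect, only these 2 of the 17 tags next to ro02104 passed (4 up and 1 down adjusted over the list alone), and the list had adjusted p = 0.0587. The pRHL1 list was lower (median -0.27, 0 up and 1 down, 12 and 98 adjusted over the list alone; adjusted p = 0.00223; adjusted p = 0.283 with an estimated correlation), with a median of 0.65 without scaling and 0.76 with spike-in scaling. Its median was 0.01 with nitrogen, where the list did not pass, and -0.49 without it, so the mean rests on the starved cultures. Every contrast in which pRHL1 passed uses the starved WT arrays, which all lay on slide 2, and no contrast without them passed. The cholesterol cluster (0 up and 1 down; 1 and 1 adjusted over the list alone), pRHL2 (0 and 2 in both counts) and pRHL3 (0 and 1; 1 and 8 adjusted over the list alone) did not pass, with adjusted p = 0.982, 0.982 and 0.381. Leaving out any array moved this count of 21. It was 3, 4 and 9 without nitrogen-rich deletion replicate 1, 2 or 3, and 4, 3 and 3 without starved deletion replicate 1, 2 or 3. It was 3, 5 and 3 without nitrogen-rich WT replicate 1, 2 or 3, and 5, 3597 and 4 without starved WT replicate 1, 2 or 3. ro02103 missed the threshold in 6 of these (nitrogen-rich deletion 1, starved deletion 2 and 3, nitrogen-rich WT 1 and 3, starved WT 3; adjusted p from 0.0522 to 0.0795). Both ro02103 and ro02105 did so with quantile normalization (adjusted p = 0.0563 and 0.0578) and with the authors' table (0.0589 and 0.0669). Slide as a fixed block left 1 gene, ro02104. With that block, ro02103 was higher by 2.06 and ro02105 by 2.37 log2 units (adjusted p = 0.317 and 0.228), and within slide 1, with nitrogen, they were higher by 1.18 and 1.86.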

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

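The tests of the patterns weighed in this part were chosen after the results were seen, apart from the counts of other splits and the test of starved WT replicate 2 on the brightest genes. The nitrogen effect differed between the strains, by the interaction term, in 15 genes. The pRHL1 list had a median interaction of -0.51, a call that was lost with an estimated correlation (adjusted p = 0.459). Its median was 0.18 without scaling and 0.23 with spike-in scaling. The response also differed for the named genes ro11204, ro11207 and ro11210, at 3.77, 7.47 and 7.55 log2 units. These sizes were 2.44, 5.59 and 7.22 with the common floor and 0.98, 2.45 and 4.45 with normexp and quantile normalization. Of 100 drawn splits that exchanged strain labels within each nitrogen condition, 1, the real one, gave 15 or more genes. The highest of the others gave 1 gene. This does not exclude chance for the gene count, since the draw left out splits known to give more. Exchanging all strain labels of the starved arrays turns the interaction into the mean strain effect with the same p-values. The real split so exchanged gives the 21 genes of that effect, and another gives 1846, so the share depends on the draw. At an unadjusted p under 0.05 by limma the real split gave 1962 genes and 3 others gave more, up to 2458 in a split with 0 genes at the adjusted threshold. For the number of gene lists called chance is not excluded: 49 of the 100 splits gave as many lists, and the highest gave 2 where the real split gave 1. That count takes any list, so it does not test the pRHL1 list itself.

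The range ro11201 to ro11217 on pRHL3 carried 11 of the 15 genes called over all arrays. Far more genes were called without starved WT replicate 2, so that share depends on keeping this array. A change in copy number of the whole plasmid would move its other genes alike, and the median interaction of the other 232 pRHL3 genes was -0.12 (SD over genes 1.11) against 3.92 in the range. The median in the range was 3.57 under the common floor and 1.58 with normexp and quantile normalization. The offset in normexp shrinks log2 changes by construction, so the latter value does not measure how far the size rests on background. Dim signal is argued against by a common floor, under which 11 of the 11 genes were still called, and slide by the fit with slide as a fixed block, in which 9 of the 11 were. A change in copy number of the range alone would likewise move its tags alike. Their interactions ran from -1.37 for ro11216 to 8.39 (SE 1.08) for ro11202, and among the called tags from 3.02 (SE 0.50) for ro11203. This spread argues against such a change as the only cause. A candidate explanation left open is that the range is regulated in a way that depends on strain and nitrogen, which was not tested. Copy number itself was not measured.

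Starved WT replicate 2 lay with the starved deletion arrays. Measured on 2127 genes above background on all arrays and at least 2-fold apart between the other starved WT arrays and the starved deletion arrays, it had moved 77.7% of the way to the deletion profile. A mix with RNA of the starved deletion strain at that share would put ro02104 at -2.14 log2 units relative to the other starved WT arrays, and it lay at 0.59. Dim signal on the other arrays is argued against by the brightest 1707 genes, where its mean correlation with the starved deletion arrays exceeded that of the other starved WT arrays by 0.37 (bootstrap SE 0.02), against 0.32 over all genes. Slide does not separate the 3 starved WT arrays, which share one; a difference between cultures, for example in how far starvation had gone, may remain and was not tested.

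ro02103 and ro02105, on either side of the deleted gene, were higher in the deletion strain averaged over both nitrogen conditions, though neither passed with nitrogen alone. Array brightness as the cause is argued against by quantile normalization, which left changes of 1.71 (SE 0.28) and 1.93 (SE 0.33) in place of 1.90 and 2.21; the calls ended there (adjusted p = 0.0563 and 0.0578) with changes still far larger than their SE. A local effect at the deleted gene stays open: both adjacent tags were among 8 genes called higher, and the chance for 2 given genes is 1.2e-06, but these tags were singled out because they were called, so that value decides nothing. In starved cultures, ro02107, ro02108 and ro02111 were called as well (log2 changes of 1.26, 1.40 and -1.51), but that comparison called 42.8% of all genes, so these calls do not show how far such an effect would reach. A regulatory effect of the missing protein on its neighbours was not tested.

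For each of the 4 pairwise comparisons, 3 arrays against 3 allow 10 splits, too few for a share under 0.05. The real split alone (1 of 10) gave as many genes: 1263 for starvation in WT, 1952 for starvation in the deletion strain, 5 for the deletion with nitrogen and 2922 for the deletion without it. The highest other split gave 0 genes in each (by limma at an unadjusted p under 0.05, 1979, 298, 510 and 2476, against 2236, 3115, 213 and 3696 in the real split, so for the deletion with nitrogen other splits gave more). For gene lists in the same order, 4, 4, 1 and 6 of the 10 splits gave as many lists as the real 2, 1, 2 and 1, and the highest other split gave 2, 2, 0 and 2. For the mean strain effect, 4 of 100 splits gave 21 or more genes, the highest other split giving 1846. At an unadjusted p under 0.05 the real split gave 2684 and 3 others more, up to 3139. The share of 4 in 100 is under 0.05 but depends on which splits were drawn, as for the interaction, so it does not exclude chance. Counts so far above the real one point to a structure of the samples, so this share alone does not tie the count of 21 to the strain. 6 of the other splits kept the starved groups whole and mixed the nitrogen-rich arrays: 3 of them gave 1846, 1097 and 888 genes, and the other 3 gave 0 (by limma at an unadjusted p under 0.05, 1959 or more in each of the 6). For its gene lists, 54 of 100 splits gave as many as the real 1, and the highest gave 2, so chance is not excluded.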

How the results depend on the processing

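Samples with the same replicate number did not deviate together (correlations of deviations -0.33 to 0.32 over 18 pairs, with the own number best in 7 of 36 comparisons), so the numbers were not taken as pairs. With the replicate number as a block, 1085 genes (starvation in WT), 1581 (starvation in the deletion strain), 5 (deletion with nitrogen), 2548 (deletion without nitrogen), 11 (interaction) and 4 (mean strain effect, 21 without the block) were called. No named gene called in a comparison changed direction under any alternative run, nor did the direction of a called list's test. The medians of called lists did turn: those of pRHL1 for the deletion without nitrogen, the interaction and the mean effect and of pRHL3 for the deletion with nitrogen, without scaling and with spike-in scaling, and that of the cholesterol cluster in the deletion strain under both other filters. Normexp was run on median spot signals; lists were not tested with slide as a random block, and array weights rested on 1 array with a weight of 35.9. The dim signal of the WT arrays limits genes near background. Except where stated, causes were not tested.

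Without scaling, 3119, 4207 and 1 genes were called for starvation in WT, starvation in the deletion strain and the deletion with nitrogen, and 3592 for the mean strain effect. Spike-in scaling, chosen after seeing the data, gave 838, 2976, 1 and 3875. Median centring gave 11 and quantile normalization 2 genes for the mean effect. Normexp gave 1287 for starvation in the deletion strain, 1 and 1443 for the deletion with and without nitrogen, and 12 for the mean effect. The authors' table gave 9 for the interaction and 2 for the mean effect. The common floor, also chosen after seeing the data, gave 1, 1613, 54 and 102 for the deletion with and without nitrogen, the interaction and the mean effect.

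With no dim filter the mean effect had 5 genes. With only probes above background on all arrays, which leaves 3658 genes, the counts were 669 (starvation in WT), 1, 1830, 8 and 920 (deletion with and without nitrogen, interaction, mean effect). Array weights gave 3861, 3929, 9, 5470, 3550 and 4105 in the order of the blocked counts, and the trended prior gave 622 for the mean effect. Fits over 6 arrays gave 566, 3457, 1 and 1015 for the pairwise comparisons, in place of 1263, 1952, 5 and 2922. The reported fit shares 1 spread per gene over all groups. The median gene's SD was 0.37 in nitrogen-rich WT, 0.67 in starved WT, 0.34 in the nitrogen-rich and 0.27 in the starved deletion strain. The shared spread therefore tends to understate that of starved WT and to overstate that of the deletion groups. With slide as a fixed block the counts were 525, 1287, 1, 3, 9 and 1, and as a random block the mean effect had 1892. The random block estimated a correlation of -0.15 between arrays of a slide, so that count does not speak against an effect of slide. Leaving out each array gave 752 to 2666, 859 to 3147, 1 to 9, 604 to 4372, 9 to 3091 and 3 to 3597 genes in that order, and a correlation of the nitrogen responses of 0.253 to 0.696.

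Normexp gave that correlation as 0.659 (0.505 otherwise). An estimated correlation left 1 of 8 list calls. The gap in ro02104 between the lowest WT and the highest deletion array, 5.89 log2 units, was 4.17 without scaling, 1.91 with normexp, 4.33 with spike-in scaling and 3.56 with the floor, which lifts dim values by construction. The offset in normexp shrinks this gap by construction as well. Every other count, including those at 2-fold or more and with the brightest probe per gene, stayed within 1.5 times of the count reported.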

Other observations

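The runs of adjacent tags described in this part, and the shuffles that test them, were chosen after the values were seen. The shuffles treat tags as independent, so they show only that neighbouring tags were called together, whatever the cause. Starvation changed genes in long runs of neighbouring tags. In WT, 13 runs of at least 6 tags moved in the same direction, 7 up and 6 down, and the longest had 24 tags; in 1000 shuffles of the tag order the longest run was 7 and no shuffle had more than 1 such run. In the deletion strain there were 17 runs, 10 up and 7 down, with a longest run of 19 against 8 in the shuffles. The tags ro02126 to ro02131 rose in WT by a median of 24.8-fold and ro02126 to ro02132 in the deletion strain by 102-fold, with tags below background at their bounds. These sizes depend on how background is treated: the log2 medians, 5.38 and 6.98 with no bounds, were 3.36 and 4.76 with the common floor and 1.82 and 2.49 with normexp and quantile normalization. The 13 tags ro01468 to ro01480 fell in WT by a median of 3.97-fold (log2 -1.99, and -0.99 without scaling), and 7 of them were also called lower in the deletion strain.

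In the cholesterol catabolism cluster, besides ro04508 to ro04518, the deletion strain had runs of rising tags at ro04536 to ro04546 (6 tested tags, median 7.50-fold with tags at their bounds) and at ro04575 to ro04580 (6 tags, median 14.5-fold). Their log2 medians of 2.95 and 3.86 were 1.44 and 1.78 with normexp and quantile normalization. The latter run was also higher in the starved deletion strain than in starved WT, by a median of 3.86-fold (log2 1.95, and 0.92 with normexp and quantile normalization). In WT, 5 of its 6 tags rose with starvation.

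The strain difference under starvation had a shorter longest run than either nitrogen response. It had 30 runs of at least 6 tags, 6 up and 24 down, where the shuffles gave 1.18 on average and at most 5. 1 of the falling runs, ro07273 to ro08004, joins the last tested tags of the chromosome to the first of pRHL1, so 29 runs, 6 up and 23 down, each lie within a single replicon, while the shuffles took no account of replicons. The longest run had 9 tags, while a shuffle reached 10, although 2922 genes were called. The size of the falls depends on the scaling and on how background is treated, though their sign held under each such setting tried. The medians of the 24 falling runs lay between -1.95 and -1.45, but between -0.69 and -0.18 without scaling and between -0.55 and -0.04 with spike-in scaling. They lay between -1.38 and -0.25 with the common floor and between -0.53 and -0.17 with normexp and quantile normalization. Without scaling, 3519 genes were called higher and 19 lower. With slide as a fixed block 3 genes were called, and as a random block 3411. The random block estimated a correlation of -0.15 between arrays of a slide, so its larger count does not speak against an effect of slide.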
